A study of Mus musculus with 11 samples.

How the data were processed

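Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where RFX1, RFX2 and RFX3 sit on DNA in mouse ependymal cells, the multiciliated cells that line the brain ventricles. RFX proteins are winged-helix transcription factors that bind a DNA element called the X-box. The cells were differentiated ex vivo from the lateral walls of brains of wild-type OF1 mice; the labels give the tissue as embryonic and the age as P0. The series holds 11 samples, of which 6 were ChIP samples (2 per RFX) and 5 were input chromatin (2 each for RFX1 and RFX2 and 1 for RFX3). Per the labels, each RFX was pulled down with its own antibody, and the RFX2 antibody came from a different lot in each replicate. Chromatin was sonicated and TruSeq libraries were made, per the labels' protocols.

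For each RFX, 1 list of reproducible peaks was used, with the replicates of an RFX already merged. The submitters' processing notes name CASAVA 1.8.2, Bowtie 0.12.7, MACS2 2.0.10.20130520 and the genome build GRCm38, without saying which step each served. How a peak qualified as reproducible, which sample served as control and how many reads lay behind each list are not given in the sources used here. The deposited score of a peak is the whole part of 10 times its −log10 q, which held for all peaks of the 3 lists. The deposited fold enrichment is the value that the narrow-peak layout gives for enrichment of the peak. It was read here as a ratio of ChIP signal to background. The deposited −log10 q is the peak caller's q-value on a −log10 scale. The deposited summit offset gives the position of the strongest signal within the peak. These values belong to the authors' peak calling and were used mainly to describe, rank, filter or group peaks within their own list. Between lists, −log10 q was correlated at shared peaks and set against overlap with another list. Medians, and fold differences between gene ends and other peaks, were also set side by side. A further value column per list (1 in each), the −log10 p, was not used.

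With replicates merged, no replicate error could be given and no replicate could be left out. Sequencing depth is unknown, so intervals on shares (95%, exact Clopper-Pearson) cover the counting of peaks or genes only. A peak that is missing from a list was not called there; that is not evidence that the factor was absent. Longer lists reach weaker sites, so the main comparisons were repeated after each list was shortened to its best 1250 peaks, the length of the RFX2 list. These were the overlap, regions, gene-end shares, bound genes and gene list tests. Gene-end shares by class of region are given at full list length unless another setting is named.

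Peaks of a pair of lists were called overlapping when they shared at least 1 bp. The overlap was set against 1000 random placements of the second list within the same chromosomes, with a one-sided permutation p; the lowest p that these placements can give is 0.000999. Chromosome bounds for the placements came from the gene and peak coordinates. Peaks of all 3 lists were merged into regions and each region was classed by the lists it held. The −log10 q of peaks that overlapped another list was compared with that of peaks that overlapped none by a two-sided permutation test with 100000 resamples.

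Genes came from a RefSeq gene table of GRCm38.p6, with 21887 protein-coding genes on assembled chromosomes. The table gives no strand and no transcript starts. The planned promoter window of 1 kb around a start site was therefore replaced by 1 kb around either annotated end of a gene, called a gene end here. A gene was called bound when a summit lay within 1 kb of either of its ends, so a bound end can be a start or a 3′ end. The share of summits at gene ends was compared with 1000 random placements of the same list by permutation and with the first placement by Fisher's exact test. Bound genes were compared between RFX, and between 20 fixed gene lists and all other protein-coding genes, with two-sided Fisher's exact tests. The difference between a pair of RFX within a gene list was tested with an exact McNemar test. The share of genes of 1 RFX kept by a second RFX was compared between list members and the rest with Fisher's exact test. Benjamini-Hochberg adjustment covered 6 ordered overlaps, 60 list tests, 60 within-list tests and 120 tests of the kept share; the threshold was an adjusted p of 0.05. Genes are not independent replicates, so these p-values describe the lists of these samples.

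The gene lists were fixed before the data were examined, as were the tests, most alternatives and the rule for naming genes. Of 434 list members, 431 matched the gene table and 3 did not. An alias that paired the wrong gene with Dnaaf9 was removed after the gene table was read. The lists hold intraflagellar transport complex A, complex B and their motors, the BBSome, the transition zone, dynein arms, dynein arm assembly, radial spokes with the nexin-dynein regulatory complex and central pair, basal body and centriole genes, the multiciliated cell programme, RFX genes, planar cell polarity, hedgehog signalling, MHC class II, ribosomal proteins, the proteasome, and markers of neurons, astrocytes, oligodendrocytes and microglia. Pooling the ciliary lists (201 genes, planar cell polarity included) and using ribosomal protein plus proteasome genes as a control pair were chosen after seeing the data, as was the kept share of the pooled ciliary lists, adjusted over 6 ordered pairs. The naming rule took 15 regulators whatever their values, the 5 genes with the best peak at a gene end per RFX, 2 members per list bound by all 3 RFX and 2 bound by RFX1 or RFX3 but not RFX2, the 3 best genes of each class bound by a single RFX, and members of a list where 5 or fewer were bound or unbound. Single genes or peaks named outside this rule are said to be chosen after their values were seen. Some genes that the rule names are not reported here.

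Alternatives varied the overlap rule (50% of the shorter peak, reciprocal 50%, summits within 200 bp), the peaks kept (the better-scoring 50%, or 1250 per list), the window (500 bp, 5 kb, or the nearest gene end at any distance) and the background genes (only genes bound by at least 1 RFX). Alternatives without peaks under a fold of 4, and without genes bound only through a peak shared with a neighbour, were added after seeing the data, as was the share of peaks at gene ends in lists of 1250. No genome sequence was used here, so X-box and other motif searches, strata by CpG content and windows around the 5′ end alone were not run.

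Overlap and list tests were first tested on simulated data. For RFX1 peaks with RFX3 peaks, 40% planted overlap returned 40.1% of 7440 peaks and 0% planted returned 0.188%. For list enrichment in RFX3 over 21887 genes, lists of 12 genes bound at 8 times the background rate were called in 88.5% of draws, and lists of 25 in 100%. At 3 times the background rate, lists of 12, 25 and 40 genes were called in 7%, 23.5% and 39% of draws. At 1 times the background rate they were called in 0%. A simulated list was called by a Bonferroni rule over the number of list tests, not by the Benjamini-Hochberg adjustment used for the reported lists. These percentages are therefore not the power or false-call rate of the reported list tests, which were not simulated. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9. Coordinates are 1-based on GRCm38.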

Results

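Binding sites of RFX1, RFX2 and RFX3 were mapped by ChIP-seq in ependymal cells differentiated ex vivo from wild-type OF1 mouse brain. The design used 2 independent ChIP replicates per RFX and 5 input samples, and asked which sites each RFX occupies. RFX1 had 7440 reproducible peaks, RFX2 had 1250 and RFX3 had 9318. Their median widths were 319, 416.5 and 256 bp, and they covered 2493.85, 560.617 and 2643.35 kb. Each list was already merged over its replicates, so no value below carries a replicate error. The number of reads behind each list is not given in the sources used here.

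The best 5 peaks of each list lay in regions held by all 3 lists, which does not make them the best peaks of the other lists. The best RFX1 peak lay on chromosome 7 at 83580901–83581388, 3817 bp from Tmc3, a transmembrane channel-like gene, with a −log10 q of 277.567 and a fold enrichment of 46.5. An RFX3 peak at the same place (83580929–83581380) was the second best of that list, with a fold of 59.4. The best RFX3 peak, on chromosome 16 at 9280957–9281358, was 286759 bp from the nearest gene end, that of the glutamate receptor subunit gene Grin2a; an RFX1 peak there ranked 3 in its list. The best RFX2 peak lay inside Tox2, an HMG-box gene, on chromosome 2 at 163205441–163206574 with a fold of 34.5. The genes near these peaks were named after their values were seen.

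The median −log10 q was 29.1 for RFX1, 30.1 for RFX2 and 19.9 for RFX3, and the lowest value kept was 12.03, 18.2 and 8.87. Median fold enrichment was 7.51, 9.96 and 7.45. Peaks with a fold under 4 numbered 99 in RFX1, 6 in RFX2 and 903 in RFX3. The highest running number among the peak names was 10149, 3493 and 14030, of which the lists held 73.3%, 35.8% and 66.4%. Relative to protein-coding genes, RFX3 peaks were densest on chromosome 12, with 74.1 peaks per 100 genes, against 19.6 on chromosome X; these densities were not tested.

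Nearly all RFX2 sites were also RFX1 and RFX3 sites. Of the 1250 RFX2 peaks, 1237 (99.0%, interval 98.2 to 99.4) overlapped an RFX1 peak and 1224 (97.9%, 97.0 to 98.6) an RFX3 peak. In the other direction, 1238 RFX1 peaks (16.6%, 15.8 to 17.5) and 1228 RFX3 peaks (13.2%, 12.5 to 13.9) overlapped RFX2. RFX1 and RFX3 shared more of their longer lists: 5524 RFX1 peaks (74.2%, 73.2 to 75.2) overlapped RFX3, and 5527 RFX3 peaks (59.3%, 58.3 to 60.3) overlapped RFX1. Random placement gave between 2.84 and 17.5 overlapping peaks on average. The permutation p was 0.000999 in each of the 6 directions, before and after adjustment, which is the smallest that the placements can give. Placements were uniform along each chromosome, so this p cannot separate shared RFX sites from open chromatin that both lists favour. With 1250 peaks in every list, 68.5% of RFX2 peaks overlapped RFX1 and 57.9% overlapped RFX3, and 56.5% of RFX1 peaks overlapped RFX3.

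Merging gave 11236 regions. RFX1 and RFX3 together held 4298 of them (38.3%), all 3 factors held 1221 (10.9%), RFX3 alone 3788 (33.7%) and RFX1 alone 1900 (16.9%). The remaining regions were few: 16 with RFX1 and RFX2, 10 with RFX2 alone and 3 with RFX2 and RFX3. Among the 10 regions with RFX2 alone, 5 had a fold between 2.24 and 3.61; the best, on chromosome 17 at 4626154–4626715, had a fold of 30.5 and lay 367916 bp from Arid1b, a chromatin remodelling gene. The regions with RFX2 alone were singled out after their values were seen. With 1250 peaks per list the regions with RFX2 alone rose to 254, those with RFX1 alone fell to 272 and those with RFX3 alone fell to 404.

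**Figure D1:**
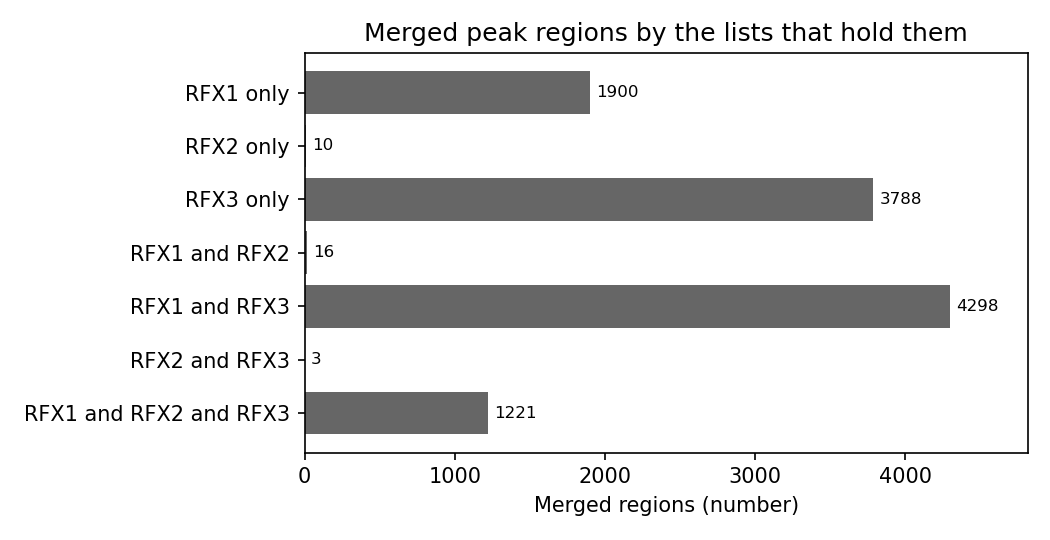
Number of merged regions (x axis) by the combination of RFX1, RFX2 and RFX3 peak lists that each region holds (y axis). RFX1 with RFX3 is the most frequent class with 4298 regions, and 10 regions hold RFX2 alone.

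Where peaks overlapped, their summits lay close together. The median distance between summits was 12 bp for RFX1 and RFX2, 16 bp for RFX1 and RFX3 and 18 bp for RFX2 and RFX3, and 94.0%, 90.5% and 88.5% of shared peaks had summits within 50 bp. Ranks of −log10 q at shared peaks correlated across peaks, with Spearman's rho of 0.587, 0.577 and 0.463 and Pearson's r on a log scale of 0.586, 0.599 and 0.492. The permutation p of each rho was 1.0e-05, the smallest that the resamples can give; peaks are not independent replicates.

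For RFX1 and RFX3, the share of sites held in common rose with −log10 q. In the top decile of RFX1 peaks, 81.7% (78.8 to 84.4) overlapped RFX2 and 99.7% (99.0 to 99.97) overlapped RFX3. In the bottom decile, 0 of 744 overlapped RFX2, which allows a share of up to 0.495%, and 43.0% (39.4 to 46.7) overlapped RFX3. The top decile of RFX3 peaks overlapped RFX1 in 98.2% and RFX2 in 65.5%, and the bottom decile in 20.5% and 0.859%. RFX1 peaks that overlapped another list had a median −log10 q of 37.0 against 17.8 for those that did not, and RFX3 peaks 30.1 against 13.6. Both differences had a permutation p of 1.0e-05, the smallest possible (adjusted p = 1.5e-05). By fold enrichment the medians were 8.38 against 6.16 in RFX1, but 7.70 against 7.42 in RFX3, where the area under the curve was 0.528 for fold and 0.813 for −log10 q. For RFX2 the medians of −log10 q were 30.1 and 28.2 (permutation p = 0.955), with 10 peaks in the second group.

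**Figure D2:**
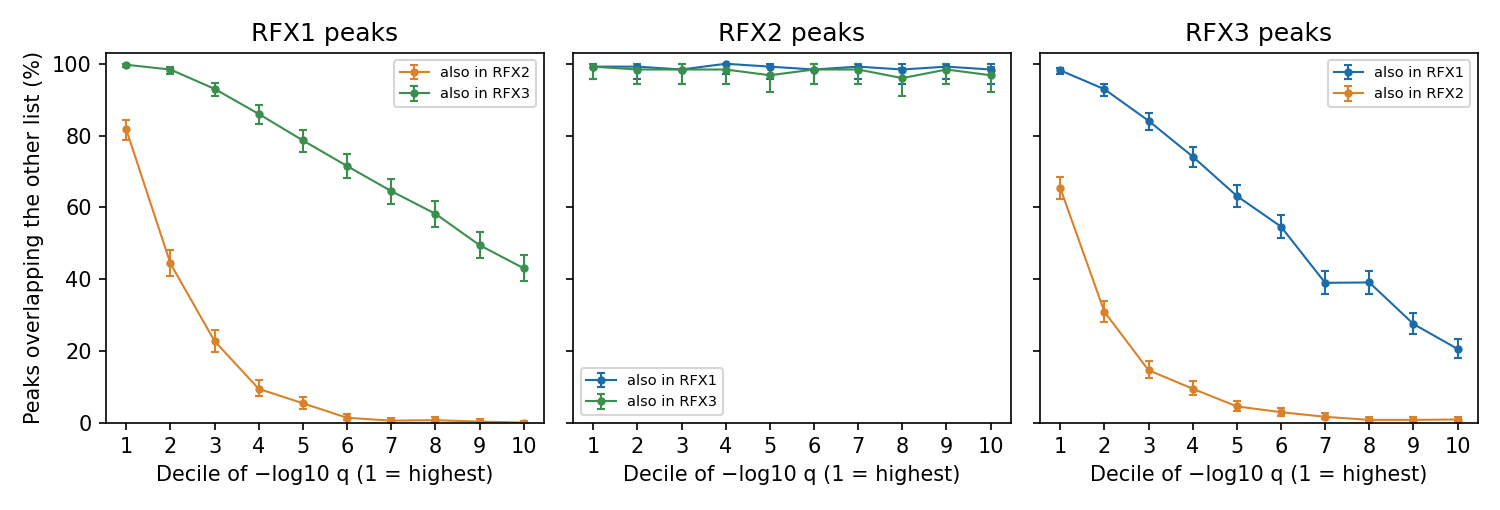
Share of peaks (y axis, percent) that overlap each other RFX list, by decile of −log10 q within the list (x axis, 1 is the strongest); bars are 95% exact binomial intervals. Overlap of RFX1 peaks with RFX2 falls from 81.7% in the top decile to 0% in the bottom decile.

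Summits lay at the ends of protein-coding genes more often than random placement gave. Summits within 1 kb of a gene end made up 1677 RFX1 peaks (22.5%, 21.6 to 23.5), 368 RFX2 peaks (29.4%, 26.9 to 32.1) and 1488 RFX3 peaks (16.0%, 15.2 to 16.7). Random placement gave 3.14%, 3.18% and 3.09%, so the observed shares were 7.19, 9.25 and 5.16 times higher. Each had a permutation p of 0.000999, the smallest the placements can give, and Fisher's exact odds ratios against the first placement were 9.46, 14.5 and 6.27. Of the remaining RFX1, RFX2 and RFX3 summits, those inside a gene made up 43.0%, 41.7% and 43.1% of all peaks and those outside genes 34.4%, 28.9% and 40.9%. With 1250 peaks per list the shares at gene ends were 44.1% for RFX1, 29.4% for RFX2 and 30.0% for RFX3, so the order of RFX2 against RFX1 and against RFX3 depended on list length.

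**Figure D3:**
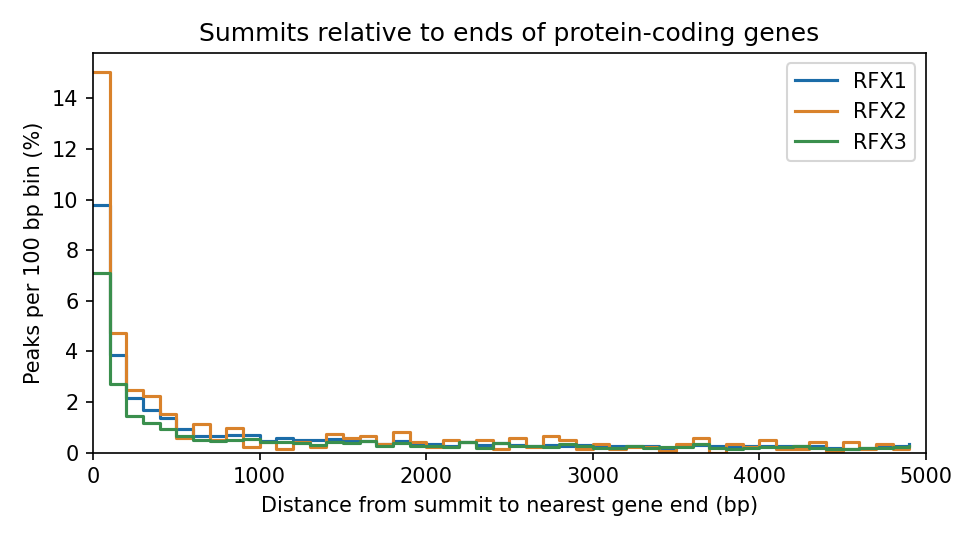
Share of all peaks of each RFX list (y axis, percent) by distance of the summit to the nearest end of a protein-coding gene (x axis, bp, in steps of 100 bp up to 5 kb). The first 100 bp hold 9.80% of RFX1, 15.0% of RFX2 and 7.09% of RFX3 peaks.

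Sites of RFX3 without RFX1 lay at gene ends less often than those with RFX1, though most sites of either kind lay elsewhere. Random placement of the whole RFX3 list gave 3.09% at gene ends. Of RFX3 peaks in regions with RFX3 alone, 6.05% were at a gene end, against 20.7% in regions with RFX1 and RFX3 (odds ratio 4.06, Fisher's exact adjusted p = 8.42e-86) and 30.0% in regions with all 3 (odds ratio 6.67, adjusted p = 1.69e-95). RFX1 peaks alone were at gene ends in 21.8%, above RFX3 alone (odds ratio 4.33, 3.63 to 5.17, Fisher's exact adjusted p = 3.56e-65). In the RFX1 list, regions with all 3 factors reached 30.1%, above the 20.8% of RFX1 with RFX3 (odds ratio 1.64, Fisher's exact adjusted p = 2.93e-11) and above RFX1 alone (odds ratio 1.55, adjusted p = 2.71e-07). RFX1 with RFX3 did not differ from RFX1 alone by the same test (odds ratio 0.942, Fisher's exact adjusted p = 0.380); the odds ratio was 1.03 with a 500 bp window and passed the threshold at 5 kb (0.842, adjusted p = 0.00319). Among the better-scoring 50% of RFX1 peaks, the odds ratios of all 3 factors against RFX1 with RFX3 and against RFX1 alone were 1.02 and 0.791, and neither passed the threshold (adjusted p = 0.815 and 0.104, Fisher's exact).

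The genes with the strongest peaks at an end were shared between the lists. Tmx4, a thioredoxin-related membrane protein gene on chromosome 2 (134594501–134644121), led the RFX1 and RFX2 lists with −log10 q of 250.802 and 195.263. Cfap65, a cilia and flagella associated gene on chromosome 1 (74902071–74935626), led RFX3 with 237.182, and the summits of RFX1, RFX2 and RFX3 lay 7, 5 and 14 bp from its end. A single peak on chromosome 3 served both 4933434E20Rik and 1700094D03Rik, with −log10 q of 234.343, 190.883 and 216.716. Glipr1l3 had an RFX3 fold of 58.8 at 1 bp from its end. Ccdc30, a coiled-coil gene, Sema4b, a semaphorin gene, and Mapre3, which encodes a microtubule plus-end binding protein, were also among the best 5 of a list. Each gene named here had a peak of all 3 factors.

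RFX1 was bound at 1980 genes (9.05% of protein-coding genes), RFX2 at 455 (2.08%) and RFX3 at 1738 (7.94%). All 455 RFX2 genes were RFX1 genes (odds ratio infinite, lower bound 1600), and 451 (99.1%) were RFX3 genes (odds ratio 1763, interval 682 to 6511). RFX1 and RFX3 shared 1507 genes, 76.1% of the RFX1 genes and 86.7% of the RFX3 genes (odds ratio 271, 229 to 322). Fisher's exact p was too small for double precision in all 3 pairs. Both ends were bound in 29, 1 and 30 genes, and 673, 174 and 542 genes were bound only through a peak that a neighbour shares. With 1250 peaks per list the odds ratios of the 3 pairs were 917, 229 and 248 for RFX1 with RFX2, RFX1 with RFX3 and RFX2 with RFX3.

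Of the 2211 genes bound by any RFX, 1056 had RFX1 and RFX3, 451 had all 3, 469 had RFX1 alone, 231 had RFX3 alone and 4 had RFX1 and RFX2. Among RFX1 alone, the zinc finger gene Glis3 on chromosome 19 had the best peak at an end (−log10 q of 88.3), followed by the urate transporter gene Slc22a12 (78.4) and Asb1 (77.2). Among RFX3 alone, 2900026A02Rik (67.7), Ice2 (63.2) and Dpy19l1 (60.3) were best. No gene was bound by RFX2 alone.

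Genes of the cilium were bound far more often than other genes. Of 201 genes in the ciliary lists, RFX1 was bound at 125 (62.2%, 55.1 to 68.9), RFX2 at 47 (23.4%, 17.7 to 29.9) and RFX3 at 120 (59.7%, 52.6 to 66.5). Other genes were bound in 8.55%, 1.88% and 7.46%. Odds ratios were 17.6, 15.9 and 18.4, with Fisher's exact adjusted p of 7.63e-79, 8.91e-36 and 4.89e-79. All 3 factors were bound at 47 of these genes, at least 1 at 130 and none at 71. Of the 20 lists, 9 were bound above other genes by RFX1, and 9 by RFX2 and 9 by RFX3, and these were the same 9.

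Intraflagellar transport genes, which encode the particles that carry cargo along the axoneme, were bound in most cases. In complex A, RFX1 and RFX3 were each bound at 5 of 6 genes and RFX2 at 2 (Fisher's exact adjusted p = 9.56e-05, 5.28e-05 and 0.0141 for RFX1, RFX3 and RFX2). Ift122 on chromosome 6 and Wdr35 on chromosome 12 had all 3 factors, Ift140, Wdr19 and Ift43 had RFX1 and RFX3, and Ttc21b had none. The RFX1 summit of Wdr35 lay 50 bp from the gene end, the RFX2 summit 32 bp and the RFX3 summit 44 bp. In complex B, RFX1 was bound at 12 of 17 genes, RFX3 at 11 and RFX2 at 4 (Fisher's exact adjusted p = 7.80e-09, 3.64e-08 and 0.000965). Ttc26 and Traf3ip1 had all 3, Ift52 and Ift81 had RFX1 and RFX3, and Hspb11, Ift46, Ift74, Ift80 and Cluap1 had none. Of 9 motor genes, RFX1 was bound at 5, RFX3 at 6 and RFX2 at 2 (Fisher's exact adjusted p = 0.00145, 5.28e-05 and 0.0313); the cytoplasmic dynein genes Wdr34 and Tctex1d2 had all 3, Dync2li1 and Wdr60 had RFX1 and RFX3, and Dync2h1, Kif3a and Kifap3 had none.

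The BBSome, a coat complex for ciliary membrane proteins, and the transition zone at the ciliary base were also bound above other genes. RFX1 was bound at 11 of 13 genes in the BBSome list, RFX3 at 9 and RFX2 at 5 (Fisher's exact adjusted p = 1.59e-09, 3.58e-07 and 1.60e-05). Not every gene in that list encodes a subunit of the coat. Bbs1 on chromosome 19 (4886878–4906653) had RFX1, RFX2 and RFX3 peaks with folds of 19.4, 16.0 and 8.81, and Arl6 also had all 3. Bbs4 and Bbs9 had RFX1 and RFX3, and Mkks and Bbs10 had none. In the transition zone RFX1 and RFX3 were each bound at 18 of 24 genes and RFX2 at 7 (odds ratios 30.4, 35.1 and 19.7; Fisher's exact adjusted p = 1.22e-13, 2.46e-14 and 1.88e-06). The tectonic genes Tctn2 and Tctn1 had all 3 factors, with RFX3 −log10 q of 131.638 and 95.4, while the Joubert syndrome genes Ahi1 and Tmem216 had RFX1 and RFX3.

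Genes of ciliary motility were bound above other genes in each of their lists. Of 26 dynein arm genes RFX1 was bound at 19, RFX3 at 18 and RFX2 at 4 (Fisher's exact adjusted p = 7.29e-14, 1.22e-13 and 0.00479). Efcab1 and Ccdc151, both tied to outer arm docking, had all 3 factors, and Dnah12, an inner arm heavy chain gene, and Wdr63 had RFX1 and RFX3. Among 15 genes for dynein arm assembly, RFX1 and RFX3 were each bound at 9 and RFX2 at 5 (Fisher's exact adjusted p = 4.82e-06, 1.88e-06 and 3.38e-05). Lrrc6 and Dnaaf3 had all 3, and Zmynd10 and Pih1d2 had RFX1 and RFX3. Radial spoke, nexin-dynein regulatory complex and central pair genes had RFX1 at 32 of 43, RFX3 at 31 and RFX2 at 14 (odds ratios 29.7, 30.5 and 23.4; Fisher's exact adjusted p = 2.06e-23, 2.06e-23 and 8.95e-13). Rsph4a, a radial spoke head gene, and Hydin, a central pair gene on chromosome 8 (110266968–110610253), had all 3, and Cfap43 and Cfap70 had RFX1 and RFX3.

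Basal body and centriole genes were bound above other genes as well, with RFX1 at 13 of 30, RFX3 at 11 and RFX2 at 4 (odds ratios 7.73, 6.75 and 7.30; Fisher's exact adjusted p = 3.07e-06, 3.38e-05 and 0.00790). Cep162 and the distal appendage gene Fbf1 had all 3 factors, and the subdistal appendage gene Odf2 had RFX1 and RFX3. Of the 9 enriched lists, complex A in RFX1 (odds ratio 6.26, adjusted p = 0.382) and basal body genes in RFX3 (1.63, adjusted p = 0.842) were no longer called by Fisher's exact test with 1250 peaks per list. In RFX2, 5 lists were called with the better-scoring 50% of peaks, and complex A (odds ratio 18.6) and dynein arms (7.48) were not called once genes bound only through a shared peak were left out. With the nearest gene end at any distance, RFX2 was no longer called in complex A (3.57), motors (5.10) and basal body genes (2.75; Fisher's exact adjusted p = 0.355, 0.119 and 0.112). A background of the 2211 genes bound by at least 1 RFX could not test single lists in RFX1, which held 1980 of them: the transition zone, bound at 18 of 18, had an adjusted p of 1 (Fisher's exact). RFX2 held 455 of the 2211, so its lists were not limited in this way, and none of the 9 passed. They held only 5 to 34 of the 2211 genes, with odds ratios from 1.03 to 4.86, so not passing can reflect their small size. The lowest Fisher's exact adjusted p in RFX2 was 0.306, for radial spoke and related genes (odds ratio 2.75). Against the same background, the pooled ciliary genes were above the other bound genes (odds ratios 3.04, 2.32 and 3.43 for RFX1, RFX2 and RFX3).

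**Figure D4:**
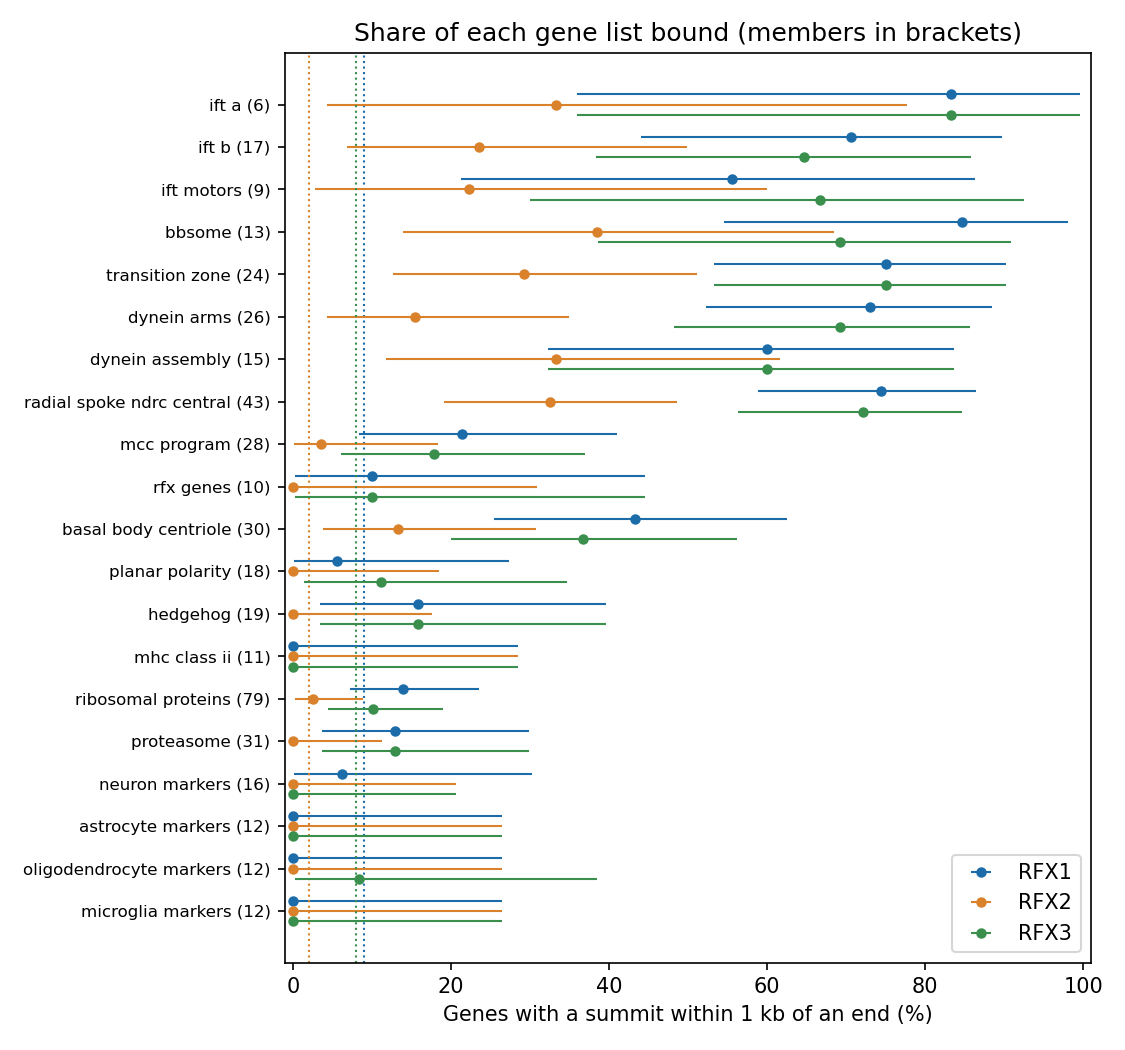
Share of each fixed gene list (y axis, members in brackets; ift is intraflagellar transport, ndrc the nexin-dynein regulatory complex, mcc the multiciliated cell) with an RFX1, RFX2 or RFX3 summit within 1 kb of a gene end (x axis, percent); bars are 95% exact binomial intervals and dotted lines mark the share of other protein-coding genes for each RFX. Radial spoke and related genes reach 74.4% for RFX1, and astrocyte and microglia markers stay at 0%.

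Foxj1, the master regulator of motile ciliogenesis, was bound by all 3 factors near its end on chromosome 11, with summits at 116335422 for RFX1, 116335441 for RFX2 and 116335418 for RFX3 and folds of 14.9, 9.87 and 7.06. Ccno, which acts in centriole amplification, had RFX1 and RFX3 summits 212 and 213 bp from its end, and Deup1, a deuterosome gene, 406 and 431 bp. The Deup1 peak of RFX1 had a fold of 3.16, near the lowest of its list. The multiciliated cell programme as a whole was not called, with 6 of 28 genes bound by RFX1, 5 by RFX3 and 1 by RFX2 (Fisher's exact adjusted p = 0.0776, 0.138 and 0.741). In RFX1 it passed the threshold with windows of 500 bp (odds ratio 3.43, adjusted p = 0.0317, Fisher's exact) and 5 kb (3.25, adjusted p = 0.0102) and with the nearest gene end (3.79, adjusted p = 0.00165). Gmnc, an upstream activator of the programme, had a peak of each RFX inside the gene, 8407, 8423 and 8387 bp from an end, with folds of 24.6, 14.1 and 27.5. Trp73 had RFX1 and RFX3 peaks inside the gene away from its ends. The nearest RFX1 summit to Mcidas was the Ccno peak, 5991 bp away, and the nearest to Myb was the Ahi1 peak, 172354 bp away.

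RFX genes carried peaks of the factors themselves, mostly inside the gene. Rfx2 had RFX1 and RFX3 summits 60 and 46 bp from its end on chromosome 17 (−log10 q of 31.3 and 66.4), and peaks of all 3 inside the gene, the best with 116, 93.4 and 75.5. Rfx1 had a peak of each factor inside the gene, 3249, 3267 and 3274 bp from an end, with folds of 22.3, 23.7 and 7.13. Rfx3 had peaks 3575, 3591 and 3581 bp from an end, with folds of 22.1, 27.1 and 9.49, and Rfx4 had peaks of all 3 inside the gene, 3023, 10901 and 10894 bp from an end at the nearest. No peak lay inside Rfx5, Rfx6, Rfx7 or Rfx8. Within 1 kb of an end, 1 of 10 RFX genes was bound by RFX1, 0 by RFX2 and 1 by RFX3, which did not pass the threshold (Fisher's exact adjusted p = 0.842, 1 and 0.842). When each peak went to its nearest gene end at any distance, RFX2 had 4 of the 10 RFX genes and passed the threshold (odds ratio 11.9, Fisher's exact adjusted p = 0.00322). That test was not matched for the stretch of genome for which a gene is the nearest. Its median was 83.5 kb for RFX genes, against 46.3 kb over all protein-coding genes.

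The remaining lists, planar polarity among them, were not called at 1 kb. Hedgehog genes were bound at 3 of 19 by RFX1 and by RFX3 (Iqce, Efcab7 and Tulp3; Fisher's exact adjusted p = 0.457 and 0.364) and at 0 by RFX2. Planar polarity genes had Wdpcp with RFX1 and RFX3 and Prickle1 with RFX3 alone (1 and 2 of 18 bound by RFX1 and RFX3, Fisher's exact adjusted p = 1 and 0.847). Ribosomal protein genes were bound at 11, 2 and 8 of 79 (Fisher's exact adjusted p = 0.327, 0.869 and 0.698 for RFX1, RFX2 and RFX3), Rpl35 and Rpl35a by all 3. Of 31 proteasome genes, Psma5, Psmb6, Psmd8 and Psmd13 had RFX1 and RFX3 (Fisher's exact adjusted p = 0.634 and 0.556). None of 11 genes in the MHC class II list was bound by any of the 3, which allows a share of up to 28.5%. Astrocyte and microglia markers were bound at 0 of 12 each; Mag, an oligodendrocyte marker, had RFX3, and Slc17a6, a neuronal glutamate transporter gene, had RFX1. When each peak went to its nearest gene end at any distance, astrocyte markers passed the threshold in all 3 factors (odds ratios 9.84, 8.93 and 8.74; Fisher's exact adjusted p = 0.000903, 0.00619 and 0.00157), as did planar polarity (5.16, 6.88 and 5.83; adjusted p = 0.00203, 0.00483 and 0.00109), and hedgehog genes passed in RFX1 and RFX3 (2.95 and 4.01; adjusted p = 0.0443 and 0.00619). These tests were not matched for the stretch of genome nearest to a gene, whose median was longer in these 3 lists than over all genes.

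RFX2 was bound at fewer genes than RFX1 or RFX3 within several lists when the lists were used at full length. All 455 RFX2 genes were RFX1 genes and 451 were RFX3 genes, so a 0 the other way was fixed or nearly fixed beforehand. The McNemar p-values against RFX2 therefore follow how many list genes the shorter RFX2 list lacked. They do not show a difference particular to a gene list. Dynein arm genes bound by RFX1 and not RFX2 numbered 15, with 0 the other way (exact McNemar adjusted p = 0.00122), and 14 were bound by RFX3 and not RFX2 (adjusted p = 0.00183, exact). Radial spoke and related genes gave 18 and 17 (exact McNemar adjusted p = 0.000458 for both), the transition zone 11 and 11 (adjusted p = 0.00977 for both, exact), and basal body genes 9 for RFX1 against RFX2 (adjusted p = 0.0293, exact). Ribosomal protein genes also gave 9 for RFX1 against RFX2 (exact McNemar adjusted p = 0.0293). No list differed between RFX1 and RFX3. With 1250 peaks per list the counts were too small for this test to tell: the lowest p, for 6 basal body genes bound by RFX1 and not RFX3 with 0 the other way, was 0.0312 (adjusted p = 1, exact McNemar).

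The share of RFX1 genes that RFX2 kept did not differ between any single list and other genes after adjustment, and 0 of the 120 tests of a kept share passed by Fisher's exact test. Some of the 120 could not pass. RFX2 genes kept by RFX1 could not differ, since all RFX2 genes were RFX1 genes, and a list without a bound gene gave no test. These still counted in the adjustment. The lowest p was for radial spoke and related genes, where RFX2 was bound at 14 of 32 RFX1 genes (43.8%) against 22.6% of other RFX1 genes (odds ratio 2.66, Fisher's exact p = 0.00934, adjusted p = 0.649). In the transition zone, RFX3 was bound at all 18 RFX1 genes, against 75.9% of other RFX1 genes (Fisher's exact p = 0.0108, adjusted p = 0.649). With the ciliary lists pooled, a test chosen after the data were seen, RFX2 was bound at 47 of 125 RFX1 genes (37.6%) against 408 of 1855 other RFX1 genes (22.0%, odds ratio 2.14, interval 1.43 to 3.16, Fisher's exact adjusted p = 0.000473). RFX3 was bound at 115 of the 125 (92%) against 1392 of the 1855 (odds ratio 3.82, Fisher's exact adjusted p = 2.20e-05). In lists of 1250 peaks the pooled odds ratios were 1.34 and 1.77, and neither passed (Fisher's exact adjusted p = 0.574 and 0.221).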

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

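The alternatives without peaks under a fold of 4, without genes bound only through a shared peak, and the share at gene ends in lists of equal length were chosen after seeing the data, as was the kept share with the ciliary lists pooled. No paired analysis was possible because the files used here hold 1 merged list per RFX, with no value per replicate; leaving out a replicate was not run for the same reason. X-box searches, strata by CpG content and windows around the 5′ end alone were not run, since no genome sequence or strand was used here. The 36 overlap, 15 gene-end share, 9 gene overlap and 3 score alternatives kept their direction and their side of the threshold. Of the list enrichment alternatives 419 did so, 43 turned, 26 were weaker, 6 stronger and 4 moved. These counts leave out settings that gave no finite odds ratio. Among those are the lists bound in full against a background of genes bound by at least 1 RFX, none of which was called there. The score difference in RFX3 was small by fold (area under the curve 0.528). In the pooled ciliary lists, all 4 kept shares that passed at full length did not pass with 1250 peaks per list: RFX1 genes kept by RFX2 (odds ratio 1.34, from 2.14) and RFX3 (1.77, from 3.82), and RFX3 genes kept by RFX1 (1.36, from 3.73) and RFX2 (1.32, from 1.93). Depth is unknown, and list length limits what can be said between RFX. Where no reason is given, the cause was not tested.

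By construction, the better-scoring 50% held 3720, 625 and 4659 peaks of RFX1, RFX2 and RFX3. It gave 904 regions with RFX1 alone, 6 with RFX2 alone, 1852 with RFX3 alone, 2198 with RFX1 and RFX3, 1 with RFX2 and RFX3, and 606 with all 3. With 1250 peaks per list these were 272, 254, 404, 122, 140 and 584, with 272 for RFX1 and RFX2. Without peaks under a fold of 4, 5 regions held RFX2 alone and 85 held RFX1 and RFX2.

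With only genes bound by at least 1 RFX as background, which leaves 2211 genes, 0 lists were called in RFX1, in RFX2 and in RFX3. In RFX1, which held 1980 of these genes, this says little, since a list bound in full could not pass. In RFX3, which held 1738, the transition zone was bound in full (18 of 18) and did not pass either. RFX2 held 455 of them, so its lists were not limited in this way. No single list passed in RFX2, though the pooled ciliary genes did (odds ratio 2.32, Fisher's exact adjusted p = 3.93e-05). The 9 lists enriched at 1 kb held only 5 to 34 of these genes, so not passing can reflect their small size. In RFX1 complex A (5 of 5), complex B (12 of 12), the BBSome (11 of 11), the transition zone (18 of 18), dynein arms (19 of 19) and dynein assembly (9 of 9) were bound in full, as were complex A, motors (6 of 6), the transition zone and dynein assembly in RFX3. In RFX1 the odds ratios of radial spoke genes (1.88) and basal body genes (1.52) fell below the threshold and motors turned to 0.582. In RFX2 this held for complex A (2.58), complex B (1.94), motors (1.93), the BBSome (3.24), the transition zone (2.48), dynein arms (1.03), dynein assembly (4.86), radial spoke genes (2.75) and basal body genes (1.55); the multiciliated programme turned to 0.771 and ribosomal proteins to 0.857. In RFX3 it held for complex B (3.01), the BBSome (1.23), dynein arms (4.94) and radial spoke genes (2.84); basal body genes turned to 0.998 and ribosomal proteins to 0.725.

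With the nearest gene end at any distance, astrocyte markers turned to odds ratios of 9.84, 8.93 and 8.74 in RFX1, RFX2 and RFX3 and were called in each, neurons turned to 2.55, 1.19 and 1.75, and oligodendrocyte markers to 1.64 and 1.62 in RFX1 and RFX2. Planar polarity turned to 5.16 in RFX1 and 6.88 in RFX2 and was called in all 3 (5.83 in RFX3). Hedgehog genes were called in RFX1 (2.95) and RFX3 (4.01) and turned to 2.10 in RFX2. Ribosomal proteins turned to 0.705, 0.950 and 0.520, and the proteasome to 0.786 in RFX1 and 0.431 in RFX3. RFX genes turned to 11.9 in RFX2 and were called. The multiciliated programme was called in RFX1 (3.79). In RFX2, complex A (3.57), motors (5.10) and basal body genes (2.75) were no longer called. This setting was not matched for the stretch of genome nearest to each gene, which differed between lists.

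With a 5 kb window the multiciliated programme was called in RFX1 (3.25), and lists below or at 1 that turned were planar polarity (2.93 in RFX1, 1.69 in RFX2), MHC class II (1.30 in RFX1, 1.39 in RFX3), neurons (1.35 in RFX1, 1.45 in RFX3), RFX genes (7.20 in RFX2) and astrocytes (1.25 in RFX3). With a 500 bp window the programme was called in RFX1 (3.43), and in RFX3 planar polarity turned to 0.859 and oligodendrocyte markers to 0. At 5 kb, 5 lists differed between RFX2 and RFX3.

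With the better-scoring 50%, 5 lists were called in RFX2; complex A (17.6), complex B (5.49), dynein arms (7.35) and basal body genes (3.03) were no longer called. In RFX3 planar polarity turned to 0.972 and oligodendrocyte markers to 0. With 1250 peaks per list, complex A in RFX1 (6.26) and basal body genes in RFX3 (1.63) were no longer called, RFX genes turned to 0 in RFX1, and in RFX3 planar polarity, hedgehog and oligodendrocyte markers turned to 0 and ribosomal proteins to 0.606.

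Without genes bound only through a shared peak, complex A (18.6) and dynein arms (7.48) were no longer called in RFX2, the multiciliated programme turned to 0 in RFX2, neurons to 1.02 in RFX1 and ribosomal proteins to 0.963 in RFX3. Without peaks under a fold of 4, hedgehog genes turned to 0 in RFX3.

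Within gene lists, 0 lists differed between RFX1 and RFX2 and 0 between RFX2 and RFX3 with 1250 peaks per list, where the counts were too small for a list to pass. The difference in bound genes between RFX1 and RFX2 was then 2 in the transition zone, 4 in dynein arms, 4 in radial spoke genes, 3 in basal body genes and 1 in ribosomal proteins, and between RFX2 and RFX3 it was 0, −4 and −2 in the transition zone, dynein arms and radial spoke genes.

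For gene ends by class in the RFX1 list, RFX1 with RFX3 against RFX1 alone turned to an odds ratio of 1.03 at 500 bp and passed the threshold at 5 kb (0.842). With the better-scoring 50%, all 3 against RFX1 with RFX3 (1.02) no longer passed and all 3 against RFX1 alone turned to 0.791.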

Other observations

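The tests of the sensitivity of the RFX2 list, of open promoters and of local background were chosen after the result was seen, as were the strata of RFX3 −log10 q for RFX2 at gene ends and of RFX3 fold enrichment for weak peaks, the pooled ciliary list and the nearest-gene stretches.

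Outside the fixed lists, 5 of 7 symbol stems named in advance were bound by RFX3 above other genes (357 tests over stems with at least 20 genes); of these, Cfap is named for the cilium. RFX3 was bound at 15 of 20 further Cfap genes (75%, odds ratio 37.7, Fisher's exact adjusted p = 7.17e-12), such as Cfap61 and Cfap69, and at 36 of 129 Ccdc genes (27.9%, odds ratio 4.90, adjusted p = 8.40e-11), such as Ccdc113 and Ccdc181. Wdr genes (12 of 58), Lrrc genes (12 of 66) and Ttc genes (8 of 36) also passed (Fisher's exact adjusted p = 0.0136, 0.0296 and 0.0380), and Kif and Tmem genes did not (adjusted p = 0.0808 and 0.724). Kif genes did pass in RFX1 (10 of 34) and RFX2 (5 of 34; Fisher's exact adjusted p = 0.00654 and 0.00672). Other stems are given here for RFX3 only. The 7 other stems that passed in RFX3, out of 119 tested, were not named in advance: Fam (29 of 174), Ap (9 of 29), Spata (9 of 30), Gtf (7 of 23), Cep (7 of 24), Dnajc (7 of 28) and Stk (6 of 22), with Fisher's exact adjusted p of 0.00130, 0.00388, 0.00488, 0.0139, 0.0172, 0.0336 and 0.0386. Olfactory receptor genes (Olfr) were bound at 1 of 1110 by RFX3 and vomeronasal receptor genes (Vmn) at 0 of 355. The microRNA genes Mir212 and Mir132 had a summit of each RFX within 1 kb of an end. The single genes named here were chosen after their values were seen.

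Astrocyte markers had no summit at an end, but 9 of 12 were the nearest gene to an RFX3 peak (Aqp4, Aldh1l1, Slc1a2, Slc1a3, Gja1, Gjb6, Fgfr3, Sox9 and Slc4a4), 9 for RFX1 and 4 for RFX2. The stretch of genome for which a marker is the nearest gene had a median of 120 kb, against 46.3 kb over all protein-coding genes. Of 18 planar polarity genes, 12 were nearest to an RFX3 peak, with a median stretch of 86.1 kb. Hedgehog and RFX genes had median stretches of 98.2 and 83.5 kb. Neuron markers had a longer median stretch, 174.5 kb, and were not called (7, 1 and 6 of 16 nearest to an RFX1, RFX2 and RFX3 peak; Fisher's exact adjusted p = 0.112, 0.647 and 0.349). This description was chosen after the data were seen.

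RFX2 peaks lay almost all within RFX1 and RFX3 peaks. Lower sensitivity of the RFX2 list stays open: RFX1 −log10 q separated peaks with and without RFX2 with an area under the curve of 0.933, and RFX3 −log10 q with 0.893, but this restates the overlap by decile, and an RFX2 that binds only the strongest sites would give the same. A preference of RFX2 for gene ends at equal strength was argued against by strata of RFX1 −log10 q (odds ratio 0.269, interval 0.215 to 0.337), but strata of RFX3 −log10 q gave 1.45 (1.22 to 1.72), and median RFX1 −log10 q was itself higher at gene ends (48.0 against 26.3); the bound set in advance, which assumed strata that do not depend on place, was dropped after these values were seen, so this stays open. A preference for ciliary genes at equal RFX1 strength also stays open, since its interval includes 1 (odds ratio 1.32, 0.756 to 2.30). Each RFX had its own antibody, so antibody and factor stay untested as sources of the difference.

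Ciliary genes were bound far above other genes. Open promoters of active genes were argued against as the whole cause only by comparison with ribosomal protein and proteasome genes. RFX3 was bound 5.47 times as often at ciliary genes as at these (interval 3.17 to 9.45), of which 10.9% were bound. The shares were known when this control pair was chosen. Of 119 symbol stems tested in RFX3 outside the fixed lists, 12 were above other genes. Ap (31.0%), Gtf (30.4%) and Dnajc genes (25%) were among these 12, so the ratio of 5.47 depends on the control pair chosen. Neither promoter opening nor expression was measured here, so other kinds of open promoter stay untested. Neighbours that share a peak were also argued against, since the RFX3 odds ratio was 20.4 (14.9 to 28.0) without genes bound only through a shared peak and 18.4 with them. No biological explanation was tested, because the design holds no cells without cilia.

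RFX3 peaks without RFX1 lay at gene ends less often than those with RFX1. Weak RFX3 peaks near the threshold were argued against as the whole cause, since at equal RFX3 −log10 q peaks with RFX1 were at gene ends more often (common odds ratio 3.17, 2.68 to 3.75). Median RFX3 −log10 q was itself higher at gene ends (31.6 against 18.7) and median fold lower (4.91 against 7.84), and strata of fold gave 4.26 (3.64 to 4.98). These strata leave out RFX1 strength, and median RFX1 −log10 q was also higher at gene ends (48.0 against 26.3). Weak RFX1 sites that were not called away from gene ends therefore stay open. A higher local background at gene ends in the RFX3 samples stays open: at equal −log10 q RFX3 fold enrichment at gene ends was lower than elsewhere by a median log2 difference of −1.16, against −0.23 in RFX1 and −0.31 in RFX2. A biological difference between RFX1 and RFX3 is untested.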
